A study of Mus musculus with 4 samples.

How the data were processed

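Small RNAs were sequenced from 4 samples of total RNA, made from the prostate of wild-type C57Bl/6 male mice aged 10 weeks. Per the labels' protocols, the gland was dissociated with collagenase and trypsin, and cells were sorted by FACS from the Sca-1 positive, lineage negative fraction. Cells with high CD49f (integrin alpha 6, a surface protein that anchors cells to the basement membrane) were taken as basal, and cells with low CD49f as luminal. Other prostate sorts commonly take luminal cells from the fraction low in or negative for Sca-1, so luminal here means only this gate as labelled. There were 2 basal and 2 luminal samples. The labels do not say whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

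The deposited table holds whole-number read counts, per the file headers, with a separate list of names and reads for each library. The counts are not normalized. The name of the table points to BLAST as the search tool. The version of that tool, the miRNA database release, the number of mismatches allowed, the adaptor trimming and the treatment of reads that matched several names are not given in the sources used here. A name with no read in a library is not listed for it, and was taken as 0 reads. Each list ends with an unnamed value equal to the sum of the values above it, which was kept out of all totals.

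The 4 lists together hold 820 names. Of these, 816 are mouse miRNAs, and the other 4 are Cali_7, Cali_12, Cali_24 and a 5' adaptor, whose nature is not given in the sources used here. These 4 names were kept out of the library totals and tests. They took 29.5% of the listed reads of basal replicate 1, 54.0% of basal replicate 2, 62.4% of luminal replicate 1 and 59.5% of luminal replicate 2. miRNA arms with similar sequence, such as the let-7 members or miR-199a and miR-199b, can share reads, and how such reads were assigned is not given in the sources used here, so values of single members of such families are uncertain.

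Counts were tested with edgeR 4.0.16 in R 4.3.3. Totals were adjusted by TMM (trimmed mean of M values), and miRNAs were filtered with filterByExpr at its default minimum of 10 reads and total of 15 reads, which left 345 miRNAs. A quasi-likelihood model with cell type as its only term was fitted, the basal over luminal coefficient was tested 2-sided, and p-values were adjusted by Benjamini-Hochberg over the 345 miRNAs with a threshold of 0.05. The standard error of a log2 fold change was computed as its size divided by the square root of the quasi-likelihood F statistic. Levels are TMM-normalised reads scaled to 1000000 miRNA reads (RPM), given as mean ± SD of 2 libraries. The test was tested on simulated data, with 200 miRNAs changed in each of 5 draws from the means, totals and spread of these libraries. The draws used 2 libraries per group and a biological coefficient of variation of 0.704. Among changed miRNAs that passed the filter, the test recovered 7.73% of changes of 2 on the log2 scale and 51.2% of changes of 4. False calls made up 2.74% of the calls. Each miRNA was drawn independently with the same spread, so this share may not hold for data with unequal or correlated spread.

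Lists of miRNAs were tested with camera in limma 3.58.1 on log2 RPM with a prior count of 2 and a preset inter-gene correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the 23 lists that had at least 3 tested members. There were 27 lists. Epithelial lists were basal or stratified epithelium, the miR-200 family, and luminal or androgen-responsive epithelium. Families and clusters were let-7, miR-17-92 and paralogs, miR-34 with miR-449, miR-29, miR-30, miR-23 with miR-27 and miR-24, miR-15 with miR-16, miR-181, miR-183 with miR-96 and miR-182, miR-10, miR-99 with miR-100 and miR-125, miR-26, miR-192 with miR-194 and miR-215, the Dlk1-Dio3 cluster and the Sfmbt2 intron cluster. Lists for cell states were hypoxia and inflammation, and lists for other cell types that the gates could hold were haematopoietic, erythroid, endothelial, smooth muscle and fibroblast, striated muscle, neural or neuroendocrine, and gut-type epithelium. In 20 simulated draws, a shift of 2 on the log2 scale given to the let-7 list was called in 20 draws and no other list was called. Each miRNA was drawn independently there. The draws therefore cannot show how often lists with correlated members are called falsely.

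The groups, tests, lists, other settings tried and the rule for naming miRNAs were chosen before the data were examined. The rule took both arms of miR-205, which was chosen because the title of the study speaks of a basal-specific microRNA. It further took up to 12 miRNAs in each direction with the largest log2 fold changes among those past the threshold with a mean of at least 50 RPM and no overlap between groups, the 5 most abundant miRNAs of each group, and the 4 most abundant members of each list. A few further miRNAs, chosen after their values were seen, are named as such. Shares of reads carry exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since the reads carry no molecular identifiers here. The floor of 3 reads corresponded to 1.12, 0.894, 2.30 and 2.44 RPM in basal replicates 1 and 2 and luminal replicates 1 and 2.

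Other settings fixed beforehand were RLE, upper-quartile and totals-only scaling, totals without the 5 most abundant miRNAs, DESeq2 1.42.0, limma-voom, no filter, a minimum mean of 10 RPM, the replicate number as a block, each library left out in turn, an adjusted p under 0.1, a fold of at least 2, and summed copies of the same mature miRNA. For lists they were an estimated correlation and fry, a rotation test. Leaving out miR-200c-3p, scaling to the Cali reads and shares of miRNA reads in place of listed reads were added after the data had been seen. Genome positions were looked up by gene name in GENCODE M21 on GRCm38, and the build used for the deposited counts is not given in the sources used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.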

Results

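The study profiled miRNAs of basal and luminal cells sorted from the wild-type mouse prostate. The prostate epithelium has an outer basal layer on the basement membrane and an inner layer of secretory luminal cells, and the comparison asks which miRNAs differ between these compartments. There were 2 libraries of each cell type. The listed reads numbered 2631926 and 7132365 in basal replicates 1 and 2, and 4211119 and 3706554 in luminal replicates 1 and 2. Of these, 1855718, 3278294, 1583830 and 1501898 were assigned to miRNAs. The libraries held 547, 548, 573 and 445 miRNAs, and 328 of the 816 miRNAs were seen in all 4 libraries. Across the 345 tested miRNAs, Pearson's correlation of log2 RPM (reads scaled to 1000000 miRNA reads) was 0.931 between the basal libraries, 0.875 between the luminal libraries, and from 0.778 to 0.876 between a basal and a luminal library. These correlations are across miRNAs, which are not independent replicates.

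The 10 most abundant miRNAs took 41.9% ± 10.1 (SD, n = 2) of the listed reads in basal libraries and 32.8% ± 1.998 (SD, n = 2) in luminal libraries. The listed reads include the Cali reads, and over miRNA reads alone the order was the reverse, at 72.6% ± 4.32 and 84.0% ± 0.691. miR-200c-3p, a member of the epithelial miR-200 family, had the most reads of the miRNAs in every library, but these reads may not come mainly from the cells. It took 22.3% (95% interval 22.2 to 22.3) and 46.9% (46.9 to 47.0) of the miRNA reads of basal replicates 1 and 2, and 68.5% (68.5 to 68.6) and 71.6% (71.6 to 71.7) of those of luminal replicates 1 and 2. With miR-200c-3p left out, the 10 most abundant miRNAs took 59.9% ± 4.38 (SD, n = 2) of the remaining miRNA reads in basal libraries and 48.8% ± 1.12 (SD, n = 2) in luminal libraries. Over the remaining listed reads, most of which were Cali reads in 3 of the 4 libraries, these shares were 29.3% ± 16.5 and 7.85% ± 0.0937. After miR-200c-3p, the most abundant miRNAs of basal libraries were miR-205-5p, miR-24-3p, miR-125b-5p and miR-126a-3p. Those of luminal libraries were miR-125b-5p, miR-200b-3p, miR-148a-3p and miR-24-3p. The Cali sequences took 29.3% and 54.0% of the listed reads of basal replicates 1 and 2, and 62.1% and 59.4% of those of luminal replicates 1 and 2. The ratio of miR-200c-3p to Cali_12 reads was 1.57 and 1.54 in basal replicates 1 and 2, and 1.62 and 1.496 in luminal replicates 1 and 2. So steady a ratio fits reads that entered in proportion to Cali_12, as set out among the results flagged for a closer look.

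**Figure D1:**
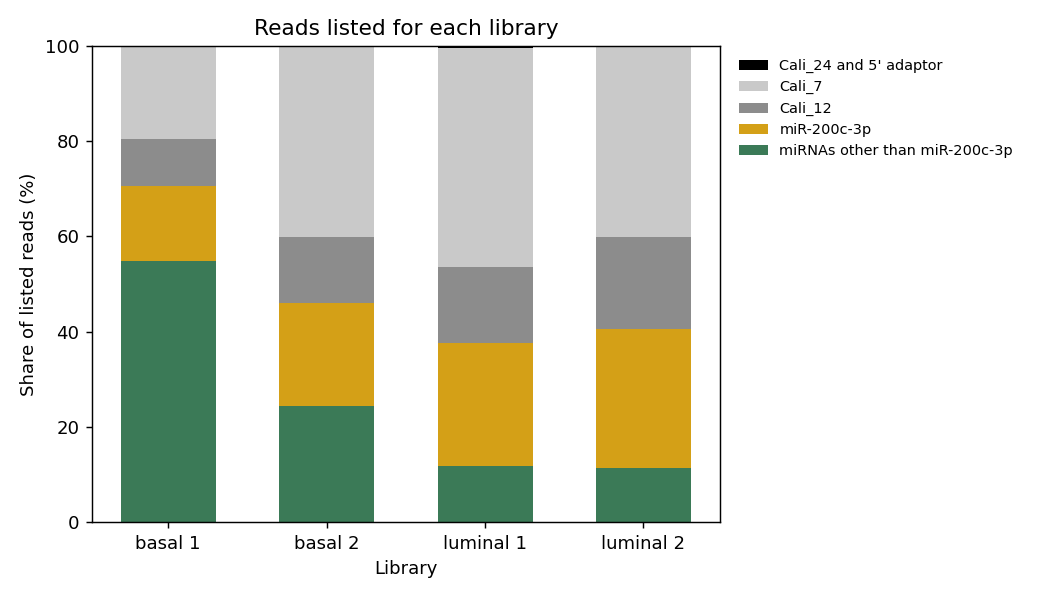
Stacked bars show the share of the listed reads of each library, in percent, matched to miR-200c-3p, to all other miRNAs and to the non-miRNA names, with 1 bar for each of the 2 basal and 2 luminal libraries. miRNAs including miR-200c-3p took 70.5% and 46.0% of basal reads and 37.6% and 40.5% of luminal reads.

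miR-205-5p, the main mature arm of a miRNA known from the basal layer of stratified and glandular epithelia, was higher in basal cells. Its level was 66481 ± 20486 RPM in basal libraries and 5650 ± 1473 in luminal libraries (mean ± SD, n = 2 each), and both basal libraries lay above both luminal libraries. The log2 fold change was 3.56 with a standard error of 0.78, an 11.8-fold difference (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0129). As a share of all miRNA reads, miR-205-5p stood at 7.89% ± 0.562 in basal and 0.465% ± 0.124 in luminal libraries (SD, n = 2 each), and with miR-200c-3p left out at 12.6% ± 4.23 and 1.54% ± 0.300. The opposite arm, miR-205-3p, stood at 49.8 ± 1.40 RPM in basal libraries and had 2 and 5 reads in luminal replicates 1 and 2. Its log2 fold change was 4.13 with a standard error of 1.30, which did not pass the threshold (adjusted p = 0.0895), but passed in DESeq2 (adjusted p = 0.0122) and without luminal replicate 1 (0.0431) or 2 (0.0176), with values up to 0.561 over all settings. On GRCm38, the Mir205 precursor lies on the minus strand of chromosome 1 from 193507463 to 193507530, within an exon of the long noncoding RNA gene 4631405K08Rik on the same strand. Without luminal replicate 2, the log2 fold change of miR-205-5p was 3.36 and no longer passed (adjusted p = 0.0718). Over its 16 alternative settings the adjusted p ranged from 1.56e-06 to that value, and it passed in the other 15. With 2 libraries against 2, an exact permutation test of any single value cannot give a p below 0.333, so all calls here rest on the spread shared across miRNAs in the model.

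**Figure D2:**
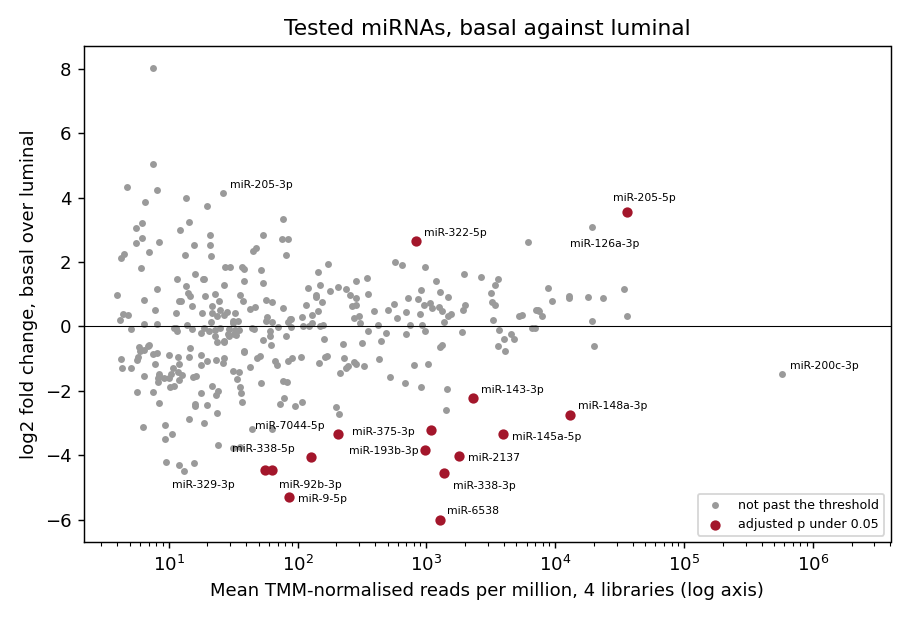
Each point is 1 of the 345 tested miRNAs, with its mean TMM-normalised RPM over the 4 libraries on a log axis and its log2 fold change, basal over luminal, on the vertical axis. Red points passed an adjusted p of 0.05, with miR-205-5p at 3.56 and miR-322-5p at 2.64 above the line and 13 miRNAs below it, while miR-200c-3p, the most abundant, lay at -1.48 and did not pass.

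Over all miRNAs, 15 of 345 differed between basal and luminal cells, 2 higher in basal and 13 higher in luminal cells. The miRNA with the other basal call was miR-322-5p, of the miR-15/16 seed family, whose members are known to restrain the cell cycle. It had 1442 ± 191 RPM in basal and 231 ± 129 in luminal libraries (mean ± SD, n = 2 each), a log2 fold change of 2.64 with a standard error of 0.65 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0236). Its precursor lies on the minus strand of chromosome X from 53054255 to 53054349, in no other annotated gene. At an unadjusted p under 0.05 there were 55 miRNAs, 22 higher in basal and 33 higher in luminal cells. In all, 178 of the 345 (51.6%) had no overlap between the groups, where chance gives 33.3% on average over all splits of the 4 libraries into 2 and 2. miRNAs of a library can vary together, so a single split can lie far from 33.3% without a group difference. The other splits were not examined. Luminal replicate 1 correlated at 0.876 with basal replicate 2 and at 0.875 with luminal replicate 2. Other scalings changed the split of 2 basal and 13 luminal calls to 3 and 10 with upper-quartile factors, 1 and 1 with library totals alone, and 3 and 0 with scaling to the Cali reads. These scalings moved the median log2 fold change of all miRNAs up by 0.300, 0.572 and 2.01. Without luminal replicate 1 there were 61 calls, 33 basal and 28 luminal, and without basal replicate 1 there were 9, 4 basal and 5 luminal. DESeq2 gave 28, 7 basal and 21 luminal. Of the 15 calls, library totals alone kept miR-205-5p and miR-6538, and scaling to the Cali reads kept miR-205-5p. The call of miR-322-5p ended without basal replicate 1 (adjusted p = 0.137), basal replicate 2 (0.0866) or luminal replicate 2 (0.172), and its adjusted p ranged from 0.00187 to 0.172 over all settings.

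Among the miRNAs higher in luminal cells, miR-148a-3p was the most abundant, at 22824 ± 3643 RPM against 3412 ± 763 in basal libraries (mean ± SD, n = 2 each). miR-148a-3p, known as androgen-responsive in prostate cells, had a log2 fold change of -2.74 with a standard error of 0.68 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0236). miR-375-3p, a miRNA of secretory and neuroendocrine cells, had 1964 ± 1424 RPM in luminal and 212 ± 25.5 in basal libraries, a log2 fold change of -3.21 with a standard error of 0.69 (adjusted p = 0.0129). miR-193b-3p was at 1810 ± 1186 against 126.4 ± 38.2 RPM (log2 fold change -3.84, adjusted p = 0.00714). The precursors of miR-148a and miR-375 lie on chromosome 6 from 51269812 to 51269910 and on chromosome 1 from 74900658 to 74900721, both on the minus strand and in no other annotated gene. That of miR-193b lies on the plus strand of chromosome 16 from 13449523 to 13449601, opposite an intron of the antisense gene Gm15738.

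Both arms of miR-338, which is encoded in an intron of the kinase gene Aatk on chromosome 11 from 120014765 to 120014862, were higher in luminal libraries. miR-338-3p stood at 2628 ± 3188 RPM in luminal and 111 ± 64.3 in basal libraries (mean ± SD, n = 2 each, log2 fold change -4.56, adjusted p = 0.0129 by edgeR with Benjamini-Hochberg adjustment), and miR-338-5p had a log2 fold change of -4.07 (adjusted p = 0.0460). The luminal libraries differed widely, with 6379 and 460 reads of miR-338-3p in luminal replicates 1 and 2. miR-9-5p, known from neural cells and encoded by 3 genes on chromosomes 3, 13 and 7, had 338 and 91 reads in luminal replicates 1 and 2, and 3 and 24 reads in basal replicates 1 and 2 (log2 fold change -5.29, adjusted p = 0.0129). miR-92b-3p (log2 fold change -4.45, adjusted p = 0.0232) and miR-329-3p of the imprinted Dlk1-Dio3 cluster (log2 fold change -4.45, adjusted p = 0.0236) were at 121 ± 78.5 and 108 ± 0.934 RPM in luminal libraries, and at 5.49 ± 2.28 and 4.85 ± 3.68 in basal libraries.

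The other luminal calls were miR-6538, miR-2137, miR-7044-5p and the smooth muscle pair miR-143-3p and miR-145a-5p. miR-6538 had the largest fold change of the 15, at 2510 ± 2103 RPM in luminal and 39.0 ± 13.5 in basal libraries (mean ± SD, n = 2 each), with a log2 fold change of -6.01 and a standard error of 0.83 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.93e-04). miR-2137 was at 3358 ± 2839 against 207 ± 129 (log2 fold change -4.02, adjusted p = 0.00849), and miR-7044-5p at 378.5 ± 166 against 37.4 ± 33.9 (log2 fold change -3.34, adjusted p = 0.0274). Mir6538 lies in an intron of Rnf144a on chromosome 12, Mir2137 in an intron of Zfp185 on chromosome X, and Mir7044 partly in an exon of Rasgef1a on chromosome 6, each on the strand of that gene. Of the luminal calls other than the smooth muscle pair, those of miR-148a-3p (adjusted p = 0.144), miR-375-3p (0.0522), miR-338-5p (0.268), miR-9-5p (0.114), miR-92b-3p (0.119) and miR-329-3p (0.337) ended without basal replicate 1. Without basal replicate 2, calls ended for miR-148a-3p (0.0773), miR-375-3p (0.113), miR-92b-3p (0.222), miR-329-3p (0.0924) and miR-7044-5p (0.303). Without luminal replicate 1 they ended for miR-338-3p (log2 fold change -1.71, adjusted p = 0.177) and miR-338-5p (log2 fold change -2.17, adjusted p = 0.150), and without luminal replicate 2 for miR-375-3p (0.123). miR-6538, miR-2137 and miR-193b-3p passed in all 4 of these runs. The call of miR-338-5p also ended with RLE factors (adjusted p = 0.0578), upper-quartile factors (0.0651), miR-200c-3p left out (0.0589) or a minimum mean of 10 RPM (0.115), and that of miR-7044-5p with upper-quartile factors (0.0793) or that minimum (0.0655).

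**Figure D3:**
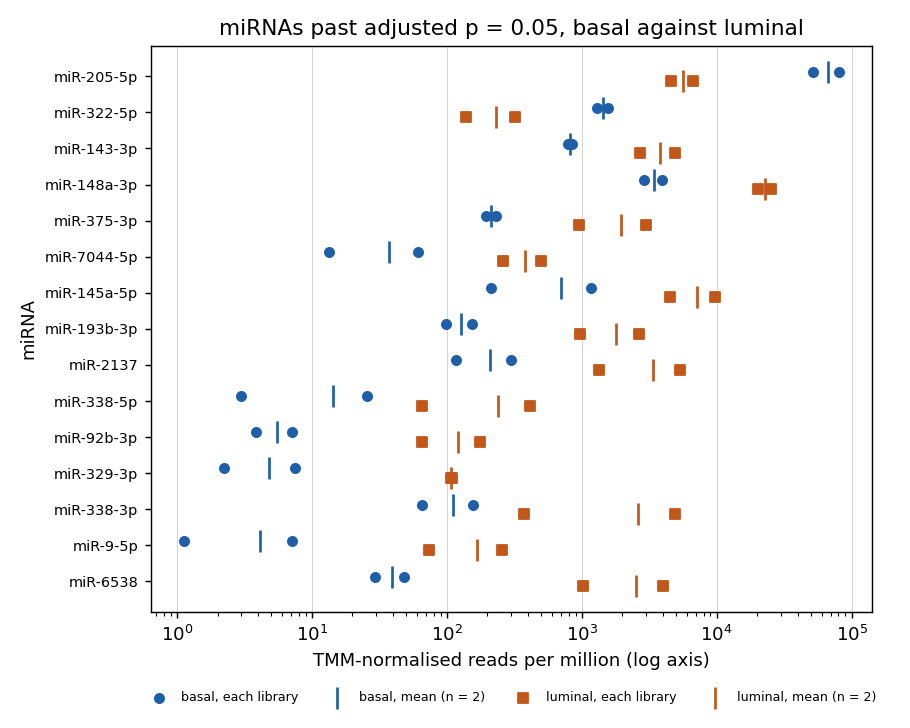
TMM-normalised RPM on a log axis are shown for each of the 15 miRNAs past an adjusted p of 0.05, with circles for the 2 basal libraries, squares for the 2 luminal libraries and vertical ticks for group means. miR-205-5p and miR-322-5p have both basal libraries above both luminal libraries, and the other 13 miRNAs the reverse.

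Of the 9 tested members of the list for basal or stratified epithelium, 1 was higher in basal cells over all miRNAs and 3 when adjusted over the list alone, which were miR-205-5p, miR-205-3p and miR-222-3p. Both miR-205 arms are on this list because of the title of the study, so the list is not independent evidence of its direction. miR-222-3p, a miRNA that targets the cell cycle inhibitor p27, had 2984 ± 267 RPM in basal and 969 ± 57.2 in luminal libraries (mean ± SD, n = 2 each, log2 fold change 1.62, adjusted p = 0.141 over all miRNAs), and its cluster partner miR-221-3p had a log2 fold change of 1.41 (adjusted p = 0.358). miR-31-5p was at 331 ± 258 RPM in basal and 368 ± 113 in luminal libraries (log2 fold change -0.15, adjusted p = 0.953), and its log2 fold change was 0.29 with library totals alone. miR-203-3p, named here after its values were seen, was higher in luminal libraries with no overlap between groups. It had 378 ± 55.3 RPM there and 175 ± 50.6 in basal libraries (log2 fold change -1.11, edgeR adjusted p = 0.391). The list median was 1.41, with 7 members above 0 and 2 below. The list ranked higher in basal cells than other miRNAs (camera, adjusted p = 0.0317, but adjusted p = 0.740 with an estimated correlation). Beside these, endothelial miR-126a-3p had 34213 ± 15173 RPM in basal and 4057 ± 4638 in luminal libraries. The list call ended without basal replicate 2 (adjusted p = 0.122) or luminal replicate 1 (0.345).

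Of the 7 tested members of the list for luminal or androgen-responsive epithelium, 2 were higher in luminal cells, miR-148a-3p and miR-375-3p, and none in basal cells. When adjusted over the list alone, these 2 passed, and so did 1 member higher in basal cells, miR-135a-5p. It had 95.4 ± 27.4 RPM in basal and 13.2 ± 10.0 in luminal libraries (mean ± SD, n = 2 each, log2 fold change 2.85, adjusted p = 0.142 over all miRNAs by edgeR), and passed over all miRNAs in DESeq2 (adjusted p = 0.0475) and without luminal replicate 2 (0.0250), with values up to 0.710 over all settings. miR-27a-3p had a log2 fold change of 1.53 (adjusted p = 0.307), and passed without luminal replicate 1 (3.08, adjusted p = 0.0208). Members went both ways, and the list was not called (camera, adjusted p = 0.670). Its median was -0.08 and its mean -0.60, and the median was 0.17 with upper-quartile factors. The miR-200 family holds the epithelial state by repressing Zeb1 and Zeb2. None of its 8 tested members passed over all miRNAs or when adjusted over the list alone. They include miR-200c-3p, whose reads may not come mainly from the cells. The family was not called (median -0.70, camera adjusted p = 0.254). The log2 fold changes of miR-200c-3p, miR-200b-3p and miR-141-3p were -1.48, -0.62 and -0.38, with standard errors of 1.02, 0.67 and 0.62 (adjusted p = 0.472, 0.698 and 0.800). All 3 were above 0 under scaling to the Cali reads, at 0.05, 1.55 and 1.82, and the family median was then 1.53. With library totals alone, miR-200b-3p stood at 0.01 and miR-141-3p at 0.24.

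The list of the miR-17-92 cluster and its paralogs, known to promote proliferation, ranked higher in basal libraries than other miRNAs, with a median log2 fold change of 0.85 over 16 tested members (camera, adjusted p = 0.0284, but adjusted p = 0.740 with an estimated correlation). No member passed over all miRNAs or when adjusted over the list alone, and 14 of the 16 had values above 0. Among them were miR-93-5p at 288 ± 75.8 and 122.4 ± 65.0 RPM in basal and luminal libraries (mean ± SD, n = 2 each, log2 fold change 1.23) and miR-25-3p at 1928 ± 599 and 1027 ± 295 (0.91). The call ended without basal replicate 1 (adjusted p = 0.0713) or luminal replicate 2 (0.0585), and the fitted median ranged from 0.66 to 1.84 in the runs without 1 library (the latter 1.34 with counts under 3 reads raised to 3). Endothelial miR-126a-3p (log2 fold change 3.08) and erythroid miR-451a (1.84) went the same way. The Dlk1-Dio3 list, an imprinted miRNA cluster on chromosome 12, ranked higher in luminal libraries, with a median of -1.85 over 17 tested members of 62 listed (camera, adjusted p = 1.74e-04, but adjusted p = 0.740 with an estimated correlation). Of the 17, 16 had values below 0, with 1 higher in luminal cells over all miRNAs and 3 when adjusted over the list alone, namely miR-329-3p, miR-127-3p and miR-541-5p. miR-127-3p had 365 ± 100.3 RPM in luminal and 55.3 ± 48.1 in basal libraries (log2 fold change -2.72, adjusted p = 0.0651), miR-541-5p 66.2 ± 21.1 and 4.85 ± 3.68 (-3.75, adjusted p = 0.0895), and miR-379-5p 41.2 ± 7.71 and 6.29 ± 8.37 (-2.69, adjusted p = 0.358). miR-379-5p had 1 and 41 reads in basal replicates 1 and 2. Its log2 fold change was -1.76 without basal replicate 1 and -6.52 without basal replicate 2. In other settings, miR-127-3p passed in 5 (adjusted p = 0.00866 in DESeq2, and up to 0.620 over all settings) and miR-541-5p in 3 (0.00671 in DESeq2, and up to 0.623). The call of this list ended without basal replicate 1 (adjusted p = 0.0713) or luminal replicate 1 (median -1.12, adjusted p = 0.0678). Without basal replicate 2 the fitted median was -5.18, and -3.49 with counts under 3 reads raised to 3, since 14 of 24 members tested in that run had fewer than 3 reads in basal replicate 1. The lists for smooth muscle and fibroblasts and for neural cells went the same way (medians -1.54 and -2.66).

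In the miR-34 and miR-449 family, which is induced by p53 and in multiciliated cells, 4 members were tested and none passed over all miRNAs, while 2 passed as higher in basal and 1 as higher in luminal cells when adjusted over the list alone. miR-34c-5p had 141.6 ± 99.99 RPM in basal and 13.8 ± 17.2 in luminal libraries (mean ± SD, n = 2 each, log2 fold change 3.35, edgeR adjusted p = 0.123), and passed in 4 other settings (0.0259 in DESeq2, and up to 0.798 over all settings). miR-34c-3p had 46 and 43 reads in basal replicates 1 and 2 and none in luminal libraries, which was at least 6.34-fold higher against a floor of 3 reads per library. miR-34a-5p went the other way, at 23.4 ± 14.6 in basal and 123.5 ± 116 in luminal libraries (log2 fold change -2.40, adjusted p = 0.218), and passed without luminal replicate 1 (0.01005). The family median was 2.07, or 1.72 with miR-34c-3p set to its bound, and the family was not called (camera, adjusted p = 0.224). Without luminal replicate 2 the fitted median was 3.37, or 2.51 with counts under 3 reads raised to 3, and the family was called as higher in basal cells (adjusted p = 0.0176, but 0.810 with an estimated correlation in that run). In the miR-15/16 family, 1 of 12 tested members, miR-322-5p, was higher in basal cells, and also 1 when adjusted over the list alone (median 0.74, camera adjusted p = 0.0651). This list was called without luminal replicate 1 (fitted median 1.80, or 1.25 with counts under 3 reads raised to 3, adjusted p = 0.0187) or basal replicate 2 (0.0335), with miR-200c-3p left out (0.0390) and over members of at least 10 RPM (0.0248). It was not called with an estimated correlation (adjusted p = 0.740). The arms of miR-322 and miR-503, from neighbouring genes on chromosome X, had log2 fold changes from 1.78 to 3.74, looked at after their values were seen. The 4 most abundant members, miR-16-5p, miR-195a-5p, miR-15b-5p and miR-15a-5p, had values from 0.20 to 0.90. All members outside that cluster ranged from -1.60 to 2.60. The calls of this list thus lean in part on 1 cluster. In the let-7 family, whose members mark differentiated cells, none of 15 passed over all miRNAs or when adjusted over the list alone, and the median was 0.65 (adjusted p = 0.141). Without basal replicate 2 the median was 1.08 and the list was called (adjusted p = 0.0170, but 0.897 with an estimated correlation in that run). let-7c-5p was at 30723 ± 15276 and let-7b-5p at 16687 ± 9072 RPM in basal libraries, against 16524 ± 868 and 9038 ± 1906 in luminal libraries.

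In 10 further families and clusters, none of the tested members passed over all miRNAs or when adjusted over the list alone, and no list was called with all 4 libraries. The median log2 fold change was -0.10 in the miR-29 family (camera, adjusted p = 0.549) and -0.04 in the cluster of miR-183, miR-96 and miR-182 (adjusted p = 0.858). With upper-quartile factors these medians were above 0, at 0.23 and 0.28. It was 0.32 in the miR-30 family (adjusted p = 0.647), 0.46 in the clusters of miR-23, miR-27 and miR-24 (0.106), 0.62 in the miR-181 family (0.255) and 0.28 in the miR-10 family (0.549). It was 0.59 for miR-99, miR-100 and miR-125 (adjusted p = 0.254), 0.76 for the miR-26 family (0.475) and 0.18 for miR-192, miR-194 and miR-215 (0.718). The Sfmbt2 intron cluster had a median of -1.41 (adjusted p = 0.718), which was 0.65 under scaling to the Cali reads. Without luminal replicate 2 its median was -2.56 and the list was called as higher in luminal cells (adjusted p = 1.93e-05, but 0.810 with an estimated correlation in that run). Without luminal replicate 1 the list was not called (adjusted p = 0.211), and 7 of its 8 members tested in that run had fewer than 3 reads in the remaining luminal library. The fitted median there was 6.17, and 1.46 with counts under 3 reads raised to 3. miR-29c-3p, which targets collagen transcripts, had 779 ± 269 RPM in luminal and 263 ± 42.3 in basal libraries (mean ± SD, n = 2 each, log2 fold change -1.57, edgeR adjusted p = 0.196). Abundant miR-24-3p and miR-125b-5p had log2 fold changes of 1.17 and 0.33 (adjusted p = 0.421 and 0.878). In the inflammation list none of 5 tested members passed over all miRNAs, and 1 was higher in luminal cells when adjusted over the list alone. It was miR-146a-5p, a feedback inhibitor of NF-kB signalling, at 2461 ± 2467 against 405 ± 28.8 RPM (log2 fold change -2.60, adjusted p = 0.0559). It passed in 6 other settings, among them DESeq2 (adjusted p = 0.0137), limma-voom (0.0201), no filter (0.0116) and the replicate block (0.0397). Without luminal replicate 2, which held 5171 of its luminal reads against 937 in luminal replicate 1, the log2 fold change was -0.77 (adjusted p = 0.773), and over all settings the adjusted p ranged up to 0.806. That list had a median of -0.95, which was 1.10 under scaling to the Cali reads (camera, adjusted p = 0.568). The hypoxia list held 2 tested members, none passing over all miRNAs or when adjusted over the list alone (median -0.99), too few for a list test.

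Of the lists for other cell types that could be tested with all 4 libraries, 2 were called, both higher in luminal libraries. The erythroid, endothelial and striated muscle lists had too few tested members for a list test, and their medians were 1.84, 2.85 and 2.99. The list for smooth muscle and fibroblasts ranked higher in luminal libraries, with all 10 tested members below 0 and a median of -1.54, which was 0.68 under scaling to the Cali reads (camera, adjusted p = 0.00995, but adjusted p = 0.740 with an estimated correlation). Of its members, 2 were higher in luminal cells over all miRNAs and 4 when adjusted over the list alone, namely both arms of miR-143 and of miR-145a. miR-145a-5p was at 7112 ± 3651 RPM in luminal and 697 ± 684 in basal libraries (mean ± SD, n = 2 each, log2 fold change -3.35, edgeR adjusted p = 0.0232), and miR-143-3p at 3820 ± 1598 and 816 ± 35.9 (log2 fold change -2.23, adjusted p = 0.0466). Their precursors lie side by side on the minus strand of chromosome 18, from 61647825 to 61647894 and from 61649196 to 61649258. The ratio of miR-145a-5p to miR-143-3p reads ranged over 14.2-fold across the 4 libraries. miR-214-3p and miR-199a-5p had log2 fold changes of -1.02 and -1.18 (adjusted p = 0.391 and 0.382), and 0.90 and 0.94 under scaling to the Cali reads. The call of miR-143-3p ended with RLE factors (adjusted p = 0.0519), upper-quartile factors (0.109), totals without the 5 most abundant miRNAs (0.0698), no filter (0.0683) or a minimum mean of 10 RPM (0.0678). It also ended without basal replicate 1 (0.337), basal replicate 2 (0.298) or luminal replicate 1 (0.154), and that of miR-145a-5p without basal replicate 1 (0.157) or with the minimum of 10 RPM (0.0584).

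The list for neural or neuroendocrine cells ranked higher in luminal libraries too, with a median of -2.66 over 6 tested members, all below 0 (camera, adjusted p = 0.0145, but adjusted p = 0.740 with an estimated correlation). Its 2 members past the threshold, and also 2 when adjusted over the list alone, were miR-9-5p and miR-375-3p, the latter shared with the luminal list. miR-128-3p had a log2 fold change of -1.27 (edgeR adjusted p = 0.548), which was 0.13 under scaling to the Cali reads. The list call ended without luminal replicate 1 (adjusted p = 0.165). Endothelial miR-126a was among the most abundant miRNAs of basal libraries. Its precursor lies on chromosome 2 from 26591357 to 26591429. It falls within an exon of Egfl7 when the exons of all annotated transcripts of that gene are pooled. Both tested members of the endothelial list, the arms miR-126a-3p and miR-126a-5p, were higher in basal cells when adjusted over the list alone, and none passed over all miRNAs. Their log2 fold changes were 3.08 and 2.63 with standard errors of 0.91 and 0.91 (edgeR adjusted p = 0.0651 and 0.127). Without luminal replicate 1 these were 5.53 and 5.87, and without luminal replicate 2 they were 2.28 and 1.76. Reads of miR-126a-3p numbered 120231 and 78829 in basal replicates 1 and 2, and 9587 and 956 in luminal replicates 1 and 2, while its adjusted p was 0.00686 with DESeq2 and ranged from 4.21e-07 to 0.258 over all settings. miR-126a-3p passed in 9 and miR-126a-5p in 5 of the other settings, the latter with values up to 0.383.

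None of the 8 tested haematopoietic members passed over all miRNAs or when adjusted over the list alone (median -0.80, or 1.0003 under scaling to the Cali reads, camera adjusted p = 0.718). Lymphoid miR-150-5p was at 4865 ± 2021 RPM in basal and 2007 ± 1168 in luminal libraries (mean ± SD, n = 2 each, log2 fold change 1.28, edgeR adjusted p = 0.351), and myeloid miR-223-3p at 35.3 ± 39.8 and 180.9 ± 214.6 (log2 fold change -2.35, adjusted p = 0.309). Without luminal replicate 2, the log2 fold change of miR-223-3p was 0.31, and without luminal replicate 1 it was -3.21 and passed (adjusted p = 0.00536). The only tested erythroid member, miR-451a, did not pass over all miRNAs or when adjusted over the list alone, at 1519 ± 1911 and 424 ± 313 RPM (log2 fold change 1.84, adjusted p = 0.346), and at a log2 fold change of -1.32 without basal replicate 2. Without luminal replicate 2 it was 2.93 and passed (adjusted p = 0.0367). In the run without basal replicate 1, 3 erythroid members were tested and the list was called as higher in basal cells (fitted median 5.89, or 3.48 with counts under 3 reads raised to 3, camera adjusted p = 0.0191, but 0.824 with an estimated correlation). None of the 2 tested striated muscle members (median 2.99) and none of the 3 gut-type members (median 0.18, camera adjusted p = 0.718) passed over all miRNAs or when adjusted over the list alone. The striated muscle members were miR-133a-3p (log2 fold change 0.96) and miR-1a-3p (fitted 5.03). miR-1a-3p had 0 and 1 reads in luminal replicates 1 and 2, so the median of 2.99 rests on a fitted value near 0 reads.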

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

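Of the tests in this part, the ratio of miR-200c-3p to Cali_12, the ratio of miR-200c-3p to miR-141-3p and the ratios of other neighbouring miRNAs were chosen only after the results had been seen, as were the values with miR-200c-3p left out and with scaling to the Cali reads.

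Reads of 4 names that are not miRNAs, outside the comparisons of the report, lay far above the 3 reads that a count of 0 allows. Averaged over the 4 libraries, Cali_7 took 36.2% of the listed reads, Cali_12 14.8%, Cali_24 0.149% and the 5' adaptor 0.144%. Cali_7 was lowest in basal replicate 1, at 19.2%, and stood at 39.8%, 46.1% and 39.8% in basal replicate 2 and luminal replicates 1 and 2. The reads of all miRNAs other than miR-200c-3p, divided by Cali_12 reads, came to 5.47 and 1.74 in basal replicates 1 and 2, and to 0.744 and 0.592 in luminal replicates 1 and 2.

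miR-200c-3p took 34.6% ± 17.4 of miRNA reads in basal and 70.1% ± 2.19 in luminal libraries (SD, n = 2 each). Its ratio to Cali_12 varied by 3.38% (coefficient of variation over the 4 libraries), against 18.9% for the steadiest and 96.7% for the median of the 131 other miRNAs with at least 1000 reads, and 12.3% for Cali_24 and 21.3% for Cali_7 against Cali_12. Against Cali_7, the most abundant Cali sequence, miR-200c-3p was less steady, at 20.2%, close to the 21.3% of Cali_7 against Cali_12. Its ratio to miR-141-3p, which is processed from the same transcript, ranged over 7.97-fold. Among 31 other pairs of miRNAs with genes at most 2000 bases apart on 1 strand and at least 1000 reads each, this range had a median of 2.76-fold, but 3 pairs (9.68%) ranged wider, up to 22.8-fold. The wider pairs were those of miR-17-5p with miR-19a-3p (22.8-fold) and with miR-19b-3p (18.9), and of miR-145a-5p with miR-143-3p (14.2). miR-17-5p had 22 reads in luminal replicate 2, while miR-145a-5p and miR-143-3p each had at least 570 reads in every library. The wider pairs are few, and those with miR-17-5p are not independent. The ratio to miR-141-3p alone does not exclude the cells' own transcript as the source. The steady ratio to Cali_12 fits reads that entered each library in fixed proportion to it, and a sequence added with it is a candidate source. The opposite arm had 10 reads in all against 4113261 of miR-200c-3p. miR-141-3p had 23.5 reads for each read of its opposite arm. Per Cali_12 read, miR-141-3p had 0.0488 and 0.0115 reads in basal replicates 1 and 2. In luminal replicates 1 and 2 it had 0.0143 and 0.00585. None of the 131 other miRNAs kept as steady a ratio to Cali_12. These values argue against the cells as the main source of the miR-200c-3p row. How large a part came from the cells was not measured. Leaving the row out gave 14 called miRNAs, all 14 among the 15.

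miR-143-3p and miR-145a-5p were higher in luminal libraries, and smooth muscle cells or fibroblasts within the Sca-1 positive, CD49f low gate are a candidate source, and the labels do not name the lineage markers that were stained. If so, the other stromal miRNAs with at least 50 RPM should be higher there too, and the 3 that qualified had a median log2 fold change of -1.02, just past the bound of -1 set for this test. They were miR-199a-5p (-1.18), miR-214-3p (-1.02) and miR-199a-3p (-0.38), with standard errors of 0.61 to 0.72, and none passed on its own. As miR-199a enters with both arms, the 3 are not separate observations. The median, again that of miR-214-3p, was -0.88 without basal replicate 1 and -0.90 without luminal replicate 2. Both fall short of the bound, which was met without basal replicate 2 or luminal replicate 1. Scaling to the Cali reads put miR-199a-5p, miR-214-3p and miR-199a-3p at 0.94, 0.90 and 1.63. This setting raised all miRNAs by a median of 2.01 and does not bear on how these 3 stood against the others. A difference between basal and luminal cells themselves stays open and was not tested.

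miR-6538, miR-2137 and miR-7044-5p carry late database numbers and were among the luminal calls, and fragments of other abundant RNAs that share sequence with the precursor could account for such counts. Of the 3 precursors, 0 shared an exact stretch of 20 bases with a transcript of an annotated gene that does not overlap the precursor. Overlapping genes were left out of the search, among them Rasgef1a, of which an exon holds part of Mir7044. Fragments of such host transcripts were therefore not tested. The search does not settle the matter for a further reason. The longest annotated ribosomal RNA gene had 2475 bases, so the full nuclear ribosomal RNA could not be searched. A difference between the cell types also stays open.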

How the results depend on the processing

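The settings with miR-200c-3p left out, with scaling to the Cali reads and with shares of miRNA reads were chosen after the data had been seen. All 15 called miRNAs kept their sign under the 16 other settings run. The number of calls was 28 with DESeq2 (7 basal and 21 luminal), 23 with limma-voom (6 basal), 23 at an adjusted p under 0.1 (5 basal) and 21 with no filter (7 basal). It was 2 with library totals alone (1 basal and 1 luminal) and 3 with scaling to the Cali reads (3 basal and 0 luminal). DESeq2 and limma-voom each kept all 15. The replicate block gave 23 calls (7 basal and 16 luminal) and left the numbers of called lists at 3 and of called marker lists at 2. Deviations of same-numbered libraries correlated at 0.153, and the labels do not say that numbers pair samples. In runs without 1 library, the lone library of its group is assumed to vary like the other group. More miRNAs enter the test in each of these runs, from 396 to 416 against 345. Calls then ranged from 9 without basal replicate 1 to 61 without luminal replicate 1, with 10 without basal replicate 2 and 27 without luminal replicate 2. Basal calls ranged from 2 to 33 and luminal calls from 5 to 28, and 6 to 12 of the 15 were kept. The log2 fold change of miR-205-5p ranged from 3.22 to 3.90 and that of miR-205-3p from 3.66 to 5.03, and miR-205-3p passed in DESeq2 at 4.11. Of 3 called lists and 2 called marker lists, 0 and 0 were called with an estimated correlation and 0 and 0 with fry, and from 1 to 4 and from 1 to 3 without 1 library, the third marker list being the erythroid list without basal replicate 1. The share of the 10 most abundant miRNAs was 72.6% in basal and 84.0% in luminal libraries over miRNA reads, and 59.9% and 48.8% over miRNA reads without miR-200c-3p. Over listed reads without miR-200c-3p, which hold the Cali reads, it was 29.3% and 7.85%, and in luminal libraries the share was 30.7% for 5 and 34.9% for 20 miRNAs.

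Among the miRNAs named in the text, changes of sign were confined to those that did not pass with all 4 libraries. Under scaling to the Cali reads, which raised all values by a median of 2.01, log2 fold changes of miR-200c-3p, miR-200b-3p, miR-141-3p, miR-31-5p, miR-29c-3p, miR-214-3p, miR-199a-5p, miR-199a-3p and miR-128-3p were 0.0497, 1.55, 1.82, 1.29, 0.58, 0.90, 0.94, 1.63 and 0.13. With library totals alone, miR-200b-3p, miR-141-3p, miR-31-5p and miR-199a-3p stood at 0.0133, 0.24, 0.29 and 0.19, and with upper-quartile factors miR-31-5p at 0.0701. Without 1 library, miR-141-3p ranged from -0.77 to 0.34, miR-31-5p from -1.29 to 0.46, miR-223-3p from -4.65 to 0.31, miR-451a from -1.32 to 2.93 and miR-199a-3p from -0.65 to 0.10. Medians of uncalled lists changed sign too. With library totals alone they were 0.39 for luminal or androgen-responsive epithelium, 0.53 for the miR-29 family and 0.57 for the cluster of miR-183, miR-96 and miR-182, and the first was 0.0252 with the replicate block. Without 1 library, medians of these 3 lists ranged from -0.65 to 1.70, from -0.39 to 0.14 and from -0.14 to 0.39. Those of the miR-10 family ranged from -0.0931 to 0.84, of miR-192, miR-194 and miR-215 from -0.35 to 0.65, of the haematopoietic list from -1.18 to 0.51, of the gut-type list from -0.23 to 3.71 and of the Sfmbt2 intron cluster from -2.63 to 6.17. The values of 1.70, 3.71 and 6.17 are fitted over members near 0 reads in luminal replicate 2, and were 0.98, 0.95 and 1.46 with counts under 3 reads raised to 3. The cause of these changes was not tested. At this depth and spread, most changes of 2 on the log2 scale would be missed, with 7.73% recovered among simulated miRNAs that passed the filter.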

Other observations

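In this part, the hypothesis on the miR-322 cluster was tested on members whose values had not been seen, and the members named beside them were chosen after their values were seen.

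miR-322 is encoded with 6 other miRNA genes on chromosome X, from 53047997 to 53054349 on the minus strand. Other arms of this cluster had more RPM in basal than in luminal libraries. miR-322-3p stood at 147 ± 72.0 and 22.3 ± 25.8 (mean ± SD, n = 2 each, log2 fold change 2.71), miR-503-5p at 36.9 ± 1.38 and 2.68 ± 3.79 (3.74), miR-542-5p at 25.9 ± 6.24 and 1.55 ± 1.05 (3.998) and miR-503-3p at 59.3 ± 2.96 and 17.2 ± 13.6 (1.78). None of these 4 passed in edgeR (adjusted p = 0.184, 0.213, 0.213 and 0.392). Without luminal replicate 1 the fitted log2 fold changes of the first 3 were 5.20, 9.50 and 4.97. These are set against 5, 0 and 1 reads in luminal replicate 2. Without luminal replicate 2 they were 1.89, 2.82 and 3.52.

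A hypothesis was that the rest of the cluster is higher in basal cells too, as members of a shared transcript would be. The 2 tested arms not looked at before, miR-351-5p (1.27 with a standard error of 0.74) and miR-450b-3p (1.47 with a standard error of 1.62), had a median log2 fold change of 1.37, above the bound of 1 set for this test, and 2 of 2 were higher in basal libraries. That median lay above 95.02% of 10000 random lists of the same size matched on mean level. Members of the random lists were drawn independently, while both arms belong to the cluster. This share therefore does not measure support for the cluster. Without luminal replicate 2 the values of miR-351-5p and miR-450b-3p were 1.06 and 0.63, with a median under the bound. Without luminal replicate 1 they were 1.65 and 4.37, with 1 read of miR-450b-3p in the remaining luminal library. Neither arm passed on its own. Both stood higher in basal libraries, as the hypothesis predicts, but the outcome against the bound rests on 2 arms and on luminal replicate 2.

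Basal replicate 2 stood apart in a few miRNAs of blood and liver. miR-451a had 9636 reads there, against 450, 265 and 794 in basal replicate 1 and luminal replicates 1 and 2. miR-144-3p, from the same erythroid transcript, had 505 reads against 6, 5 and 1, and liver miR-122-5p had 852 reads against 0, 9 and 1. Luminal replicate 2 had the highest level of myeloid miR-223-3p, at 332.6 RPM against 7.10, 63.5 and 29.1 in basal replicates 1 and 2 and luminal replicate 1, and of haematopoietic miR-142-3p, at 208.2 RPM against 27.7, 48.9 and 48.2.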
